A study of Mus musculus with 42 samples.

How the data were processed

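Ileum and liver RNA of Swiss Webster mice in 5 groups was hybridised to Affymetrix mouse exon arrays, 1 array per sample, 42 in all; the labels call the samples of a group biological replicates. The deposited values are log2, and per the submitters' processing notes they come from Affymetrix Expression Console 1.1, RMA and Partek with the mouse build mm9, named without their order. The log2 unit was checked on the values. Array medians within a tissue were close but the distributions were not identical, so the last scaling between arrays is not known, and the values were used as deposited. The values of ileum EC replicate 2 carry at most 2 decimals.

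The table holds 23332 transcript clusters. Of these, 14996 name 1 gene, 1019 name several and 7317 name none; all were tested, and only those with 1 gene are named, by the current symbol, with 14860 distinct genes. Positions are not printed, because the gene table at hand is of another build than the deposited one. All arrays gave a signal above the array medians for the Y-linked gene Eif2s3y (4.19 to 5.87 in ileum and 4.77 to 5.84 in liver), so sex was not used as a covariate. That choice rests on this gene alone.

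For each tissue, all 5 groups were fitted together with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, and 5 comparisons were tested: EC against germ-free, EC+BSH1 against EC, EC+BSH2 against EC, EC+BSH1 against EC+BSH2, and CONV-D against germ-free. P values are two-sided limma moderated tests, adjusted by Benjamini-Hochberg over all transcript clusters of a tissue and comparison, with a threshold of 0.05. Where 0 passed, the number at unadjusted p under 0.05 is given. Without any effect, a share of about 0.05 of the 23332 transcript clusters lies under that p. Such a number does not by itself show a remaining effect. Folds and log2 differences over a group mean near or below the array medians (3.06 to 3.25 in ileum and 2.73 to 2.92 in liver) are not exact. Among them are those that use Arntl in EC, EC+BSH2 or CONV-D mice of either tissue, Slc34a2, Nr0b2 or Sprr1a in EC ileum, Ube2q2 or Abca1 in EC+BSH1 ileum, Reg2 in germ-free ileum, and Cdkn1a in EC or EC+BSH2 liver. Differences between tissues were tested as interaction contrasts in a fit of all 42 arrays. The groups, comparisons, gene lists, rule for named genes and alternatives were fixed before the data were examined; those added later are named as such in the closing section.

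Named genes were, for each tissue and comparison, up to 6 higher and 6 lower genes with the largest difference among those past the threshold whose groups do not overlap, up to 3 members past the threshold from each fixed list, the 5 smallest p values where fewer than 5 named genes passed, and a fixed set of bile acid, lipid, clock and defence genes. Of 34 fixed lists with 424 members, 330 members had a transcript cluster of their own, each taken at the one with the highest mean. Symbols not found were matched through older symbols, which put Abcb1a, not a fixed member, into the FXR signalling and bile acid transport lists. The counts and list tests of both lists include it in every comparison. Lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a tissue and comparison, and members were counted over all genes and adjusted over the list alone. In the order of the comparisons, 1, 7, 2, 2 and 9 lists passed at the preset correlation in ileum and 7, 6, 3, 9 and 10 in liver, of 32 tested each, and not all of them are named. With an estimated correlation 5 passed for CONV-D in ileum, 1 each for EC+BSH1 against EC and against EC+BSH2 in liver, and 0 elsewhere. Lists with a result here cover bile acid synthesis, bile acid transport, FXR signalling, cholesterol synthesis, cholesterol uptake and efflux, fatty acid synthesis, fatty acid oxidation, the circadian clock, epithelial defence, interferon, MHC class II, acute phase, unfolded protein stress, proliferation, xenobiotic metabolism, and markers of exocrine pancreas, Paneth cells, enteroendocrine cells and smooth muscle.

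Likeness of effects with a shared control was set beside 100 simulations of unchanged groups against the same controls and beside 6 splits of the 4 controls into separate pairs. The method was tested on simulated data built from the arrays' own spread: of 50 transcript clusters moved 4-fold, 80% to 90% were recovered in each comparison, and of 50 moved 1.5-fold, 10% to 26%; 3 to 9 calls per comparison were false. A list moved on purpose was found in every comparison, and 0 of 40 random lists were called. The simulated transcript clusters were drawn independently and without a change of an array's signal range. So this check cannot tell how correlated genes or such a change affect the calls.

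The alternatives tried were quantile normalization, median centring, leaving out dim transcript clusters (below the 40th percentile of the mean), 1 transcript cluster per gene, no intensity trend, robust eBayes, array weights, all 42 arrays in a single fit, only the groups compared, the number in the array's label code as a covariate, the replicate number as a block, an adjusted p of 0.1, an added minimum of 1.5-fold, and leaving out each array in turn. Block fits used statmod 1.5.0. Added after seeing the data were a covariate for the compression of each array's signal range, leaving out 4 doubted arrays (ileum EC replicate 2 and EC+BSH1 replicates 1 and 3, and liver EC replicate 4), and comparisons of EC+BSH1 and EC+BSH2 with germ-free mice and of CONV-D with EC. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw array files and exon-level signals were not used here.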

Results

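RNA from ileum and liver of germ-free Swiss Webster mice and of 4 colonised groups was measured on 42 Affymetrix mouse exon arrays, 21 per tissue. Each tissue had 4 arrays of germ-free mice, 4 of mice monocolonised with the bacterial strain coded EC in the labels, 4 of mice with EC carrying the bile salt hydrolase gene BSH1, 4 with EC carrying BSH2, and 5 of germ-free mice that were re-conventionalised (CONV-D). Bile salt hydrolases remove the glycine or taurine that the liver attaches to bile acids, and the series asks how such bacterial bile acid modification bears on host lipid metabolism and weight gain. The deposited values are log2 RMA summaries of 23332 transcript clusters, with array medians from 3.06 to 3.25 in ileum and from 2.73 to 2.92 in liver. The spread of values within an array, which gives the signal range, was an SD of 1.94 to 2.17 in ileum and 2.08 to 2.27 in liver. It was narrowest in ileum of EC mice, with a mean SD of 2.03 (n = 4) against 2.13 in germ-free ileum (n = 4). The number of arrays limits the precision of every value below. Group values are given as mean ± SD, differences as log2 ± SE, and adjusted p values come from limma across all transcript clusters of a tissue.

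**Figure D1:**
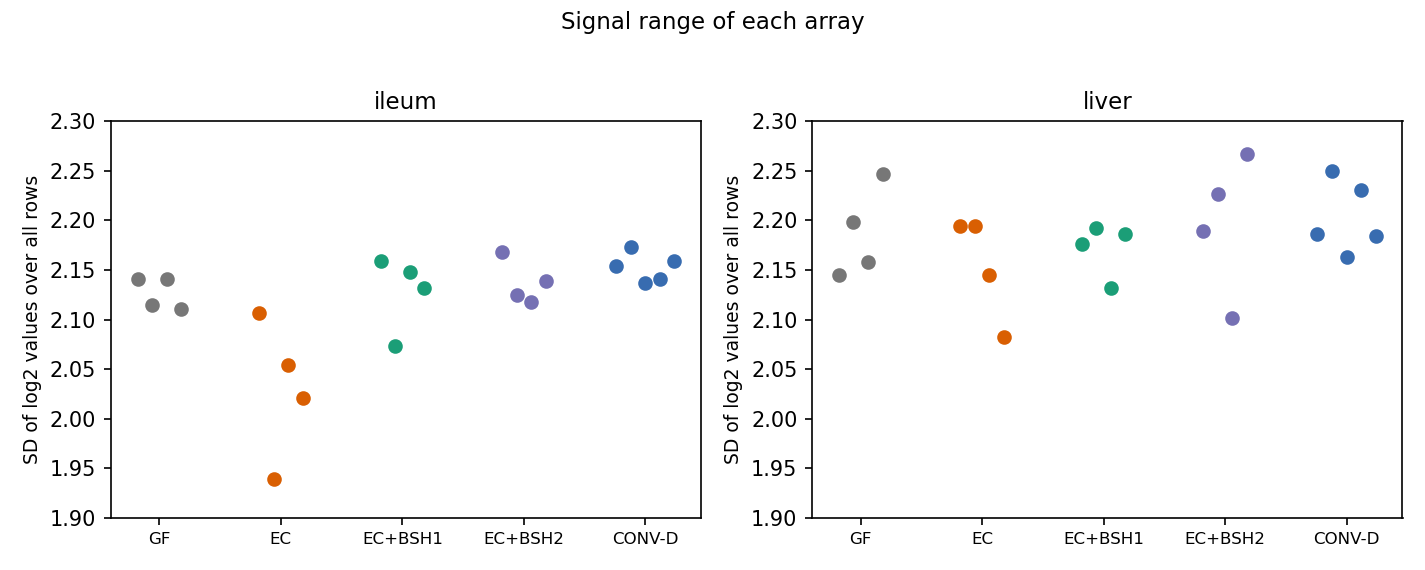
SD of the log2 values over all transcript clusters (vertical axis) of each array (points) in the 5 groups (horizontal axis), ileum on the left and liver on the right. The 4 EC ileum arrays lie between 1.94 and 2.11, and the germ-free ileum arrays between 2.11 and 2.14.

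EC mice, which carry the strain without an added hydrolase, were compared with germ-free mice. In ileum, Reg3g (transcript cluster 6954810), a secreted lectin that kills Gram-positive bacteria, rose 2.98-fold, from 7.40 ± 0.78 in germ-free mice (n = 4) to 8.98 ± 0.44 in EC mice (n = 4; adjusted p = 0.0192). Nr0b2 (6917593), the repressor SHP that the bile acid receptor FXR induces, fell 3.67-fold, from 4.55 ± 0.26 to 2.67 ± 0.23 (adjusted p = 0.00987). The sodium-phosphate cotransporter Slc34a2 fell 7.98-fold (log2 -3.00 ± 0.36) and the cornified-envelope protein Sprr1a 11.7-fold (log2 -3.55 ± 0.55). Of 12 measured members of the list of FXR signalling and targets, Nr0b2 and the basolateral bile acid exporter subunit Slc51a (log2 -0.55 ± 0.13) fell and 10 did not pass. Adjusted over the list alone, 1 rose and 2 fell, and the list as a whole did not pass (camera adjusted p = 0.395). The ileal bile acid genes Fgf15, Fabp6 and Slc10a2 did not pass in any ileum comparison. Over the 21 ileum arrays their means were 2.11 ± 0.24, 1.43 ± 0.51 and 1.35 ± 0.31, below the median of every ileum array, and Slc10a2 was higher in liver (5.21 ± 0.63, n = 21). Among 15 clock genes, the activators Arntl (log2 -1.42 ± 0.23) and Npas2 (log2 -1.13 ± 0.15) fell and the output factor Hlf (log2 0.97 ± 0.22) rose. With p values adjusted over the list alone, 5 rose and 3 fell. Smooth muscle markers were lower as a list (median log2 -0.43, camera adjusted p = 0.000624), with 1 of 9 members, Acta2, past the threshold and 4 lower adjusted over the list alone. That list call was lost at adjusted p = 0.474 with an estimated correlation.

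In all, 310 ileum transcript clusters passed in EC against germ-free mice, 16 higher and 294 lower. With quantile normalization 79 passed, 21 higher and 58 lower, so that the higher share went from 5.16% to 26.6%. The calls on Slc51a and Acta2 ended (adjusted p = 0.278 and 0.051); a covariate for each array's signal range left 3. Without germ-free replicate 3 the count was 103 and without EC replicate 1 it was 658. The calls on Reg3g and Hlf held in 4 of 8 fits and that on Slc51a in 2 of 8 fits that each left out 1 array (adjusted p up to 0.0781, 0.121 and 0.145).

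In liver, EC mice had 5.44 times the germ-free level of Cyp7a1 (6919396), the rate-limiting enzyme of bile acid synthesis: 8.91 ± 0.34 against 6.47 ± 0.39 (n = 4 each, adjusted p = 0.000474). It was the 1 of 17 bile acid synthesis genes to pass. When adjusted over the list alone 1 rose and 2 fell, and the list did not pass (camera adjusted p = 0.763). Alas1 (6998564), the rate-limiting enzyme of haem synthesis, rose 9.02-fold, from 6.48 ± 0.35 to 9.66 ± 0.29 (adjusted p = 0.000221). Clpx, a subunit of the mitochondrial protease that degrades the Alas1 protein, fell 3.30-fold (log2 -1.72 ± 0.17). Insig2, which helps to hold SREBP proteins in the endoplasmic reticulum, fell 4.02-fold. The tubulin Tubb2a fell 15.4-fold, to a widely spread EC value of 4.23 ± 1.59. Its log2 difference was -3.94 ± 0.51, and -4.38 to -3.19 with 1 array left out. Of 14 measured members of the list of unfolded protein and amino acid stress, 5 fell and 9 did not pass; the chaperone Hspa5 fell by 0.93 ± 0.15 on the log2 scale and its cofactor Sdf2l1 by 1.23 ± 0.25. Adjusted over the list alone 6 fell, and the list call (camera adjusted p = 2.84e-05) was lost at adjusted p = 0.144 with an estimated correlation. Clock genes changed both ways, 4 of 15 higher and 2 lower: Usp2 (log2 2.18 ± 0.21) and Dbp (log2 1.56 ± 0.32) rose and Arntl (log2 -1.50 ± 0.19) fell. With adjustment over the list alone 7 rose and 2 fell, and the list call (camera adjusted p = 0.000936, median above 0) was lost at adjusted p = 0.348 with an estimated correlation. Cholesterol synthesis genes were lower as a list (median log2 -0.49, camera adjusted p = 2.69e-05), with 1 of 18 past the threshold, Sc5d, and 8 lower adjusted over the list alone; adjusted p = 0.395 with an estimated correlation. Acute phase genes were lower as a list (median log2 -0.42, camera adjusted p = 1.01e-10), with 0 of 15 past the limma threshold and 10 lower adjusted over the list alone; adjusted p = 0.144 with an estimated correlation.

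The liver count was 61, with 14 higher and 47 lower. It was 103 with quantile normalization, 47 higher and 56 lower, and 30 without germ-free replicate 4. The calls on Dbp and Sdf2l1 held in 2 of 8 fits and that on Sc5d in 3 of 8 fits that each left out 1 array (adjusted p up to 0.135). With the number in the array's label code as a covariate the calls on Dbp and Sc5d ended (adjusted p = 0.092 and 0.0663).

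EC+BSH1 mice were compared with EC mice, which differ from them by design in the first hydrolase. In ileum, Slc34a2 (6930845) rose 12-fold, from 2.85 ± 0.19 in EC mice to 6.43 ± 0.86 in EC+BSH1 mice (n = 4 each, adjusted p = 4.19e-05). The EC mean lies below the median of every ileum array, so this fold is not exact. Abcb1a (6928740), the P-glycoprotein that exports drugs and toxins from enterocytes, fell 4.2-fold, from 7.34 ± 0.47 to 5.27 ± 0.36 (adjusted p = 0.00085). Nr0b2 rose 2.32-fold (log2 1.21 ± 0.34, adjusted p = 0.0437) and Slc51a 1.77-fold (log2 0.83 ± 0.13). Of the 12 genes taken for the FXR list 2 rose and 1 fell. The 1 that fell was Abcb1a, which was not a fixed member and entered through an older symbol. The counts adjusted over the list alone were the same; the list did not pass (camera adjusted p = 0.853). Of 12 genes of cholesterol uptake and efflux, the intestinal cholesterol importer Npc1l1 (log2 0.76 ± 0.12) and the oxysterol receptor Nr1h3 rose and the exporter Abca1 (log2 -0.68 ± 0.18) fell. Adjusted over the list alone 3 rose and 1 fell, and the list did not pass (camera adjusted p = 0.214). Of 15 clock genes 3 rose and 3 fell, with Arntl at log2 1.85 ± 0.23 and Dbp at log2 -1.38 ± 0.23. With adjustment over the list alone 4 rose and 7 fell. The clock list call (camera adjusted p = 0.0423, median below 0) was lost at adjusted p = 0.563 with an estimated correlation.

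Further ileum lists passed only with the preset correlation, each at adjusted p = 0.563 with an estimated correlation. Fatty acid oxidation genes were higher (5 of 17 rose, 8 adjusted over the list alone), among them Vnn1, a pantetheinase induced by PPAR alpha (log2 1.82 ± 0.35), and the peroxisomal enzyme Ehhadh (log2 0.87 ± 0.14). Interferon genes were higher (5 of 16 rose, 8 adjusted over the list alone), among them Zbp1 (log2 1.30 ± 0.29) and Irf7 (log2 0.94 ± 0.20). Unfolded protein genes (5 of 14 rose, 6 adjusted over the list alone) and MHC class II genes (2 of 4 rose, 2 adjusted over the list alone) were higher too. Smooth muscle markers moved the same way (4 of 9 rose, 7 adjusted over the list alone). Exocrine pancreas markers were lower as a list (median log2 -2.13, camera adjusted p = 0.000198) with 0 of 9 past the limma threshold and 0 adjusted over the list alone. Their mean was 3.78 in EC+BSH1 replicate 1 and 10.4 to 11.6 in the other 3 arrays, against 10.6 to 11.7 in EC mice, and without that array the list did not pass (camera adjusted p = 0.496). The MHC class II and unfolded protein calls also ended with quantile normalization (adjusted p = 0.331 and 0.4), and each ended in 5 of 8 fits that left out 1 array, as did the clock list call (adjusted p up to 0.164, 0.187 and 0.161).

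The count was 1157, with 1062 higher and 95 lower. With quantile normalization it was 256, 182 higher and 74 lower, so that the higher share went from 91.8% to 71.1%. The calls on Nr0b2 (adjusted p = 0.0834), Nr1h3 (0.206), Zbp1 (0.0684) and Irf7 (0.0824) ended. With 1 array left out the Nr0b2 call held in 1 of 8 fits, Abca1 in 2, Nr1h3 in 3 and Zbp1 in 6 (adjusted p up to 0.16). Without 3 doubted arrays (EC replicate 2, EC+BSH1 replicates 1 and 3) it was 38. A fit of the EC and EC+BSH1 arrays alone called 0 with limma, with 2981 transcript clusters at unadjusted p under 0.05 in that fit. Leaving out EC+BSH1 replicate 1 gave 412 and EC+BSH1 replicate 2 gave 1833.

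**Figure D2:**
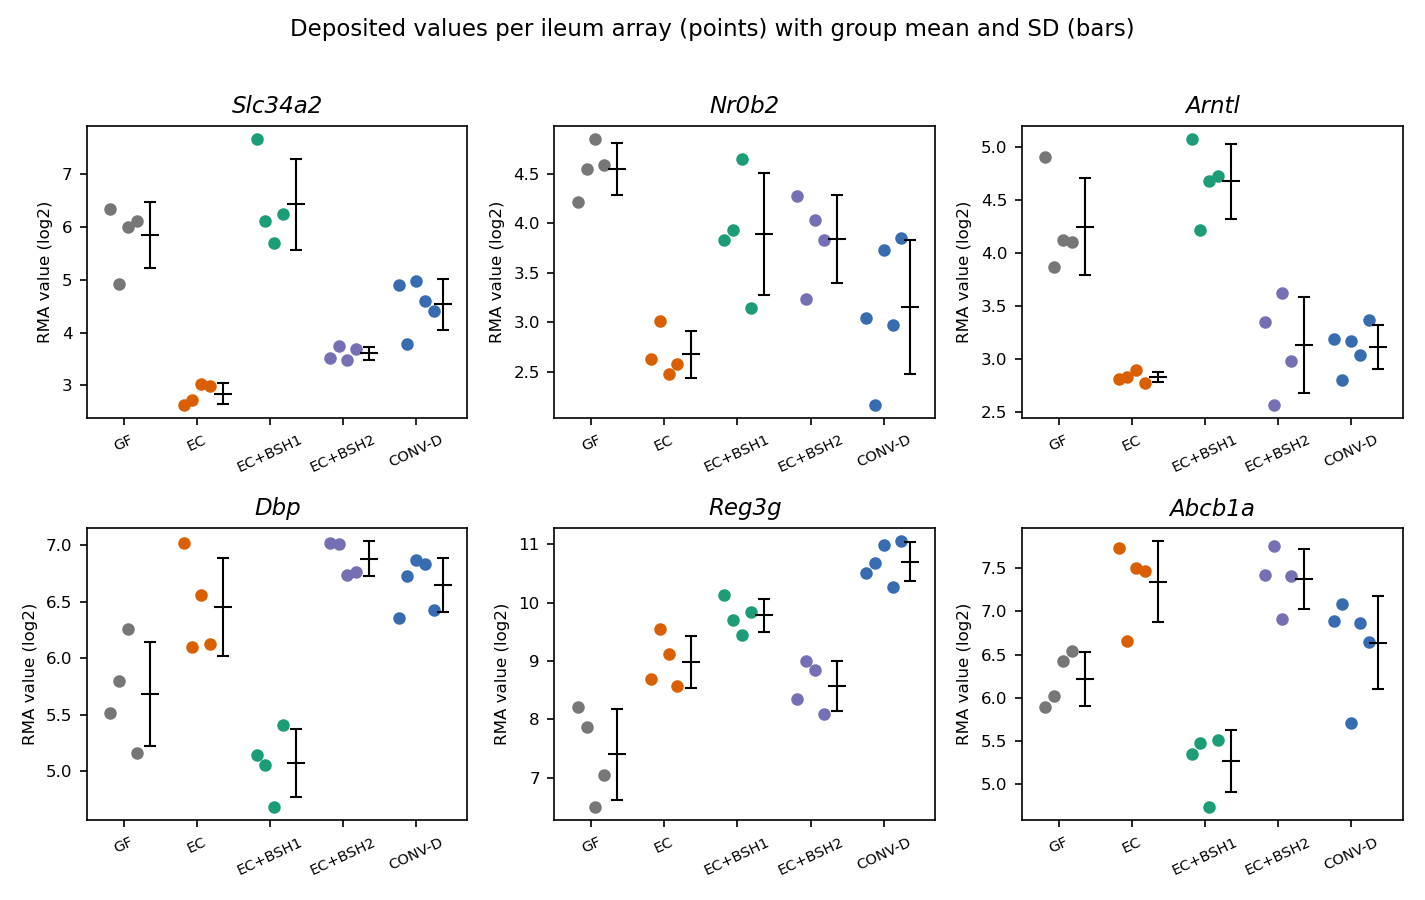
Deposited log2 RMA values (vertical axes) of 6 genes in each ileum array (points) by group (horizontal axes), with bars for the group mean and SD. Slc34a2 and Arntl lie higher in EC+BSH1 than in EC mice (6.43 against 2.85 and 4.67 against 2.83), Abcb1a and Dbp lie lower, Nr0b2 is lowest in EC mice (2.67) and Reg3g is highest in CONV-D mice (10.7).

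In liver, the clock genes gave the broadest change of a list with EC+BSH1. Of 15 measured, 5 rose, 7 fell and 3 did not pass: the activator Arntl rose 3.86-fold, from 2.11 ± 0.16 to 4.06 ± 0.29 (adjusted p = 2.14e-05), and the output factor Dbp (6960404) fell 8.28-fold, from 6.60 ± 0.38 to 3.55 ± 0.31 (n = 4 each, adjusted p = 4.03e-05). When adjusted over the list alone 5 rose and 10 fell; the list call (camera adjusted p = 6.65e-05, median below 0) was lost at adjusted p = 0.231 with an estimated correlation. Cyp7a1 fell 2.71-fold, from 8.91 ± 0.34 to 7.48 ± 0.55 (adjusted p = 0.0221), and was the 1 of 17 bile acid synthesis genes to pass. Adjusted over the list alone 1 rose and 2 fell, and the list did not pass (camera adjusted p = 0.888). Of 13 bile acid transport genes 1 fell, the canalicular exporter Abcc2 (log2 -0.50 ± 0.10); adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.267). The cell-cycle inhibitor Cdkn1a (6849595) rose 16.5-fold, from 2.76 ± 0.64 to 6.81 ± 0.20, and the fatty acid elongase Elovl3 10.2-fold (log2 3.35 ± 0.28). Tubb2a rose 18-fold from a widely spread EC value of 4.23 ± 1.59. Its log2 difference was 4.17 ± 0.51, and 3.42 to 4.61 with 1 array left out. Of 14 unfolded protein genes 5 rose, 9 did not pass, and 8 rose adjusted over the list alone: Creld2 at log2 2.03 ± 0.33, Sdf2l1 at 1.45 ± 0.25 and Hspa5 at 1.02 ± 0.15. This list held with an estimated correlation (adjusted p = 0.0282).

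Among liver lipid genes, Plin2, which coats lipid droplets (log2 0.77 ± 0.15), and the triglyceride enzyme Agpat2 (log2 0.87 ± 0.18) rose. The lipogenic factor Thrsp (log2 -1.92 ± 0.37), the mitochondrial fatty acid importer Cpt1a (log2 -0.77 ± 0.13) and the receptor Ppara (log2 -0.86 ± 0.19) fell. Acute phase genes were higher as a list (camera adjusted p = 5.34e-08; 2 of 15 rose, Fga and Fgb, and 9 adjusted over the list alone), and cholesterol synthesis genes too (camera adjusted p = 0.00526; 0 of 18 passed and 1 rose adjusted over the list alone). These calls were lost at adjusted p = 0.242 and adjusted p = 0.711 with an estimated correlation. Exocrine pancreas markers were lower in the liver arrays as well (median log2 -1.84, camera adjusted p = 0.00526; adjusted p = 0.711 with an estimated correlation), with 0 of 9 past the limma threshold and 0 adjusted over the list alone. Without EC+BSH1 replicate 1 that list and the cholesterol synthesis list did not pass (camera adjusted p = 0.174 and 0.122), nor did the former without EC replicate 4 (0.0763) or the latter without EC replicate 3 (0.128). The liver count was 173, 96 higher and 77 lower. With quantile normalization it was 303, 145 higher and 158 lower, and without EC+BSH1 replicate 3 it was 94. The calls on Cyp7a1, Ppara and Fgb held in 2 of 8 fits that each left out 1 array, those on Abcc2 and Fga in 4, that on Agpat2 in 5 and those on Plin2 and Thrsp in 6 (adjusted p up to 0.15), and the Fgb call ended with median centring (adjusted p = 0.0957).

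**Figure D3:**
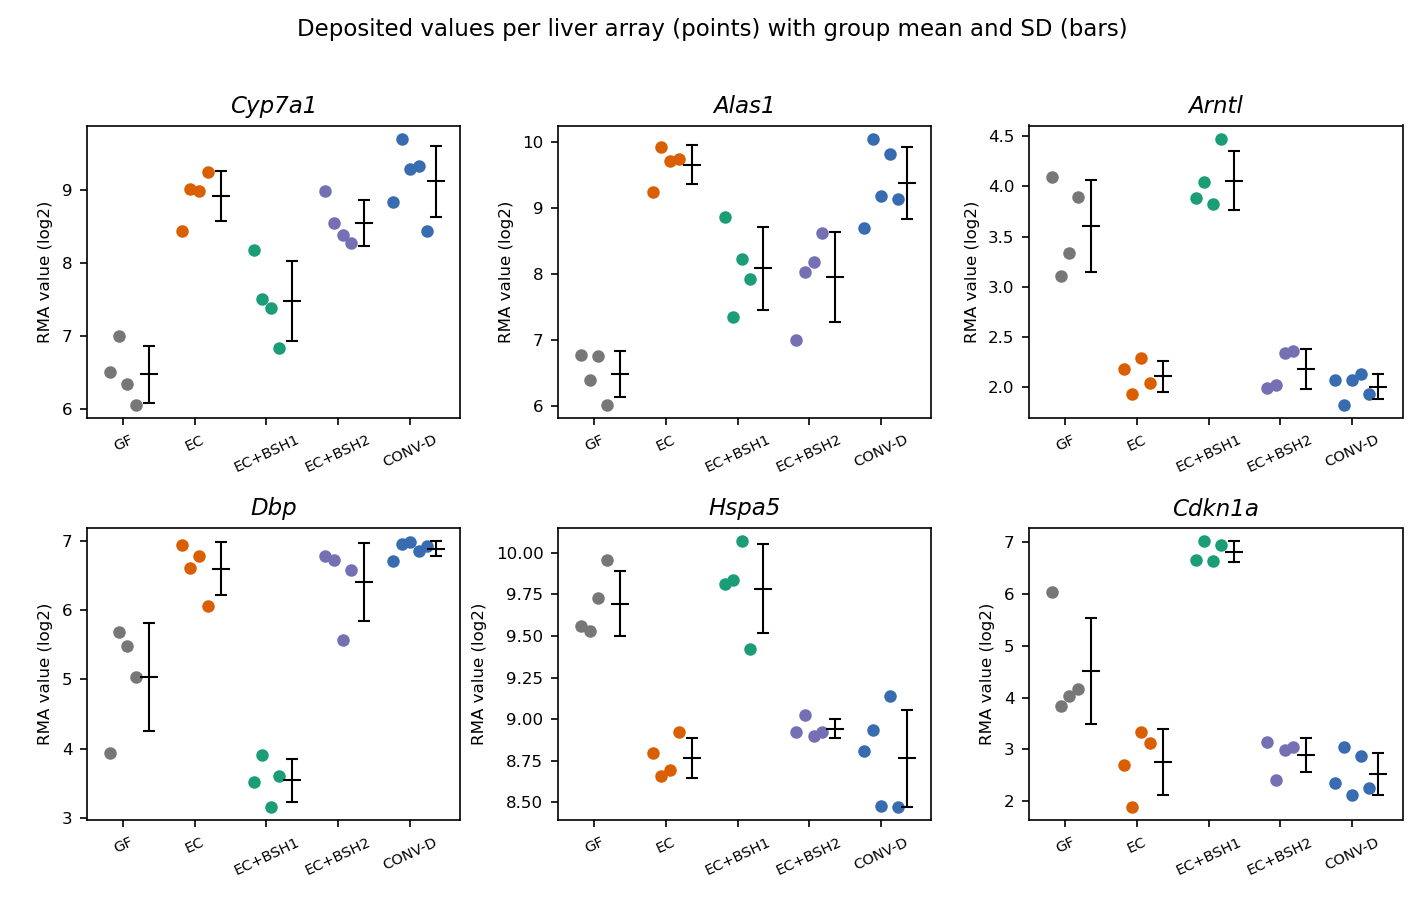
Deposited log2 RMA values (vertical axes) of 6 genes in each liver array (points) by group (horizontal axes), with bars for the group mean and SD. Cyp7a1 and Alas1 lie lowest in germ-free mice (6.47 and 6.48), and EC+BSH1 mice have the highest Arntl (4.06) and Cdkn1a (6.81) and the lowest Dbp (3.55).

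EC+BSH2 mice were compared with the same EC mice. In ileum, the median of the log2 differences of all transcript clusters was 0.11, and 0.00645 with quantile normalization. This shift is not particular to BSH2. In ileum it was 0.0917 for EC+BSH1 against EC and -0.0906 for EC against germ-free mice. With quantile normalization those 2 were 0.0157 and 0.00832. The changes below, and the ileum changes of those comparisons above, are to be read against these shifts. The carbonic anhydrase Car2 (6895856) rose 2.71-fold, from 5.04 ± 0.35 to 6.48 ± 0.44 (n = 4 each, adjusted p = 0.0172), Ehhadh rose 1.89-fold (log2 0.92 ± 0.14) and the chaperone Dnajb9 2.85-fold (log2 1.51 ± 0.28). Of the 12 FXR genes, Slc51a rose 1.49-fold (log2 0.58 ± 0.13) and 11 did not pass; adjusted over the list alone 2 rose. Nr0b2 was at 3.84 ± 0.44 against 2.67 ± 0.23 (adjusted p = 0.0952). Smooth muscle markers were higher as a list (1 of 9 rose, Acta2, and 5 adjusted over the list alone; camera adjusted p = 0.000395), and cholesterol synthesis genes too (0 of 18 passed, 0 adjusted over the list alone; camera adjusted p = 0.0036). These calls were lost at adjusted p = 0.334 and adjusted p = 0.415 with an estimated correlation. The count was 145, with 141 higher and 4 lower. With quantile normalization limma called 0 (1980 at unadjusted p under 0.05), which ended every call named here. Their adjusted p then ran from 0.112 for Ehhadh to 0.381 for Slc51a. Without EC replicate 2, EC replicate 4 or EC+BSH2 replicate 1 limma called 0 as well (2586, 3357 and 2941 at unadjusted p under 0.05). With 1 array left out the calls named held in 1 (Dnajb9) to 5 (Car2) of 8 fits (adjusted p up to 0.155). The cholesterol synthesis list did not pass with quantile normalization (camera adjusted p = 0.412).

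In liver, the protease subunit Clpx (6989922) rose 2.20-fold with EC+BSH2, from 5.87 ± 0.14 to 7.01 ± 0.21 (n = 4 each, adjusted p = 0.0483), and was the 1 transcript cluster to pass. The named genes next in rank did not pass: the kinase Sgk2 differed by log2 1.46 ± 0.26, Eps8l2 by 1.01 ± 0.19, Fbxo6 by 1.12 ± 0.21 and the tight-junction protein Cldn1 by 0.87 ± 0.17, each at adjusted p = 0.134. All 18 cholesterol synthesis genes had a difference above 0 (median log2 0.60); 0 passed over all genes and 9 rose adjusted over the list alone. Of 18 fatty acid and triglyceride synthesis genes 0 passed and 6 rose adjusted over the list alone, with the fatty acid synthase Fasn at log2 1.06 ± 0.25 (adjusted p = 0.268). Both lists passed camera (adjusted p = 5.76e-10 and 2.88e-05), and both were at adjusted p = 0.276 with an estimated correlation. Cyp7a1 was at 8.54 ± 0.31 against 8.91 ± 0.34 (adjusted p = 0.821), Arntl differed by 0.07 ± 0.19 and Dbp by -0.19 ± 0.32. Among the 15 clock genes 0 passed, and 1 rose and 1 fell adjusted over the list alone. With quantile normalization limma called 0 (1541 at unadjusted p under 0.05) and the Clpx call ended (adjusted p = 0.0625), as it did in 7 of 8 fits that each left out 1 array (adjusted p up to 0.276).

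EC+BSH1 and EC+BSH2 were also compared with each other, which shares no control group. In ileum, Slc34a2 was 7.04-fold higher with BSH1 (6.43 ± 0.86 against 3.61 ± 0.12, n = 4 each, adjusted p = 0.00284), and Angptl4 (6854971), a secreted inhibitor of lipoprotein lipase, was 3.73-fold higher (5.69 ± 0.15 against 3.79 ± 0.59, adjusted p = 0.0177). Abcb1a was 4.29-fold lower (log2 -2.10 ± 0.29), the phosphate transporter Slc20a1 2.96-fold lower (log2 -1.57 ± 0.22) and the ubiquitin-conjugating enzyme Ube2q2 5.31-fold lower. Of 15 clock genes 3 rose, with Arntl at log2 1.55 ± 0.23, and 3 fell, with Dbp at log2 -1.81 ± 0.23. Adjusted over the list alone 3 rose and 7 fell, and the list did not pass (camera adjusted p = 0.0772). Exocrine pancreas markers (median log2 -2.29; 0 of 9 passed, 0 adjusted over the list alone) and cholesterol synthesis genes (median log2 -0.16; 0 of 18 passed, 2 fell adjusted over the list alone) were lower as lists, at camera adjusted p = 0.000867 and 0.0267, and both at adjusted p = 0.542 with an estimated correlation. The count was 40, with 16 higher and 24 lower. It was 17 without EC+BSH2 replicate 1, 7 without the doubted arrays, and 19 with the number in the label code as a covariate, which runs from 3 to 19 in EC+BSH2 and from 23 to 41 in EC+BSH1 ileum. The Angptl4 call held in 6 of 8 fits that each left out 1 array (adjusted p up to 0.0781) and ended with that covariate (adjusted p = 0.121). Without EC+BSH1 replicate 1 the pancreas and cholesterol synthesis lists did not pass (camera adjusted p = 0.642 and 0.0957), and the latter did not without EC+BSH1 replicates 2 (0.114) or 4 (0.0625) or EC+BSH2 replicate 2 (0.0771) either.

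In liver, Cdkn1a was 15-fold higher with BSH1 than with BSH2 (6.81 ± 0.20 against 2.90 ± 0.33, n = 4 each, adjusted p = 0.000131) and Elovl3 4.24-fold higher (log2 2.08 ± 0.28). Of 15 clock genes 3 were higher, with Arntl at log2 1.88 ± 0.19, and 6 lower, with Dbp at log2 -2.86 ± 0.32 and Per3 at log2 -1.79 ± 0.24. When adjusted over the list alone 5 were higher and 9 lower, and the list call (camera adjusted p = 0.00114, median below 0) was lost at adjusted p = 0.334 with an estimated correlation. Of 14 unfolded protein genes 6 were higher, 8 did not pass, and 7 were higher and 1 lower adjusted over the list alone; Creld2 differed by log2 2.09 ± 0.33, and the list held with an estimated correlation (adjusted p = 0.0154). Cyp7a1 did not pass (log2 -1.07 ± 0.29, adjusted p = 0.188). Fatty acid and triglyceride synthesis genes were lower as a list (1 of 18 passed, Thrsp at log2 -1.92 ± 0.37, and 4 adjusted over the list alone; camera adjusted p = 0.000363; adjusted p = 0.334 with an estimated correlation). Exocrine pancreas markers were lower too (median log2 -2.15, camera adjusted p = 0.00159; 0 of 9 passed, 0 adjusted over the list alone), a call lost at adjusted p = 0.513 with an estimated correlation, without EC+BSH1 replicate 1 (0.082) and without EC+BSH2 replicate 3 (0.0803). In all, 9 lists passed camera here, and 1 with an estimated correlation. The liver count was 58, with 26 higher and 32 lower; with quantile normalization it was 90, 47 higher and 43 lower, and without EC+BSH2 replicate 1 it was 29. The Thrsp call held in 2 of 8 fits that each left out 1 array (adjusted p up to 0.133), and with the number in the label code as a covariate it and the Creld2 call ended (adjusted p = 0.145 and 0.0535).

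CONV-D mice, which received a whole microbiota, were compared with germ-free mice. In ileum, Reg3g rose 9.81-fold, from 7.40 ± 0.78 (n = 4) to 10.7 ± 0.33 (n = 5, adjusted p = 4.17e-05), and Reg2 (6947175), a regenerating-family protein that exocrine pancreas also makes, rose 180-fold, from 3.39 ± 1.04 to 10.88 ± 1.08 (adjusted p = 0.00438). The exocrine pancreas list did not pass (median log2 0.29, camera adjusted p = 0.651; 0 of 9 passed, 0 adjusted over the list alone). In liver, Reg2 differed by log2 3.29 (limma adjusted p = 0.35), and its effect was not shown to differ between tissues (limma adjusted p = 0.488). A change of Reg2 within pancreatic tissue in the samples was thus not separated. The glutathione peroxidase Gpx2 rose 4.1-fold and the adenosine-forming enzyme Nt5e fell 4.06-fold. Defence genes (1 of 11 rose, 3 adjusted over the list alone), interferon genes (1 of 16 rose, Zbp1 at log2 1.88 ± 0.27, and 7 adjusted over the list alone), MHC class II genes (0 of 4 passed, 4 higher adjusted over the list alone) and Paneth cell markers (0 of 3 passed, 3 higher adjusted over the list alone) were higher as lists. Enteroendocrine markers were lower (1 of 12 fell, the incretin Gip at log2 -0.67 ± 0.12, and 5 adjusted over the list alone). These 5 lists held with an estimated correlation, at adjusted p = 0.0214 for the defence, interferon and enteroendocrine lists, 0.0222 for MHC class II and 0.0487 for Paneth cell markers. Of 9 fixed Paneth cell markers 3 were measured, Mmp7, Itln1 and Pla2g2a, and none of the defensins. Itln1 and Pla2g2a are also in the defence list, so these lists are not independent. The clock genes Npas2 (log2 -1.04 ± 0.14) and Arntl (log2 -1.14 ± 0.22) fell and 13 of 15 did not pass, with 6 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.276). Nr0b2 was at 3.15 ± 0.68 against 4.55 ± 0.26 (adjusted p = 0.0802). The count was 71, with 37 higher and 34 lower; with quantile normalization it was 120, 44 higher and 76 lower, and without germ-free replicate 1 it was 38. The Arntl call held in 2 of 9 fits and the Gip call in 7 of 9 fits that each left out 1 array (adjusted p up to 0.126 and 0.0662).

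In liver, Cyp7a1 was 6.24-fold higher in CONV-D than in germ-free mice (9.11 ± 0.49, n = 5, against 6.47 ± 0.39, n = 4; adjusted p = 0.000334) and Alas1 7.43-fold higher (9.38 ± 0.55 against 6.48 ± 0.35). Of 17 bile acid synthesis genes 2 rose, Cyp7a1 and the sterol 12-hydroxylase Cyp8b1 (log2 0.69 ± 0.09), and 2 fell, among them the muricholate-forming Cyp2c70 (log2 -0.80 ± 0.13). The counts adjusted over the list alone were the same, and the list did not pass (camera adjusted p = 0.6). Of 13 bile acid transport genes 1 fell, Slc10a2 (log2 -1.33 ± 0.24), the bile acid importer of bile duct cells; adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.413). Of 14 unfolded protein genes 4 fell, 5 adjusted over the list alone, with Hspa5 at log2 -0.93 ± 0.14 (camera adjusted p = 1.46e-05; adjusted p = 0.136 with an estimated correlation). Of 15 clock genes 3 rose and 1 fell, with Usp2 at log2 1.68 ± 0.20, Dbp at 1.85 ± 0.30 and Arntl at -1.60 ± 0.18. With adjustment over the list alone 9 rose and 4 fell (camera adjusted p = 0.000936, median above 0; adjusted p = 0.159 with an estimated correlation). Fatty acid oxidation genes were higher as a list (2 of 17 rose, Cpt1a and Plin2, and 5 adjusted over the list alone; camera adjusted p = 2.73e-05; adjusted p = 0.155 with an estimated correlation). The count was 44, 13 higher and 31 lower. It was 24 without germ-free replicate 4 and 13 with the number in the array's label code as a covariate, and with that covariate, which runs from 2 to 10 in CONV-D and from 17 to 36 in germ-free liver, the calls on Dbp, Cyp2c70 and Cpt1a (each at adjusted p = 0.478), Slc10a2 (0.329), Plin2 (0.584), Cyp8b1 (0.0792) and Arntl (0.0632) ended. With 1 array left out the Slc10a2 call held in 5 of 9 fits, Cpt1a in 4 and Plin2 in 1 (adjusted p up to 0.171), and the Plin2 call ended with median centring (adjusted p = 0.0695).

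Whether an effect differed between ileum and liver was tested directly. The difference passed for 53 transcript clusters in EC against germ-free, 214 in EC+BSH1 against EC, 21 in EC+BSH1 against EC+BSH2 and 70 in CONV-D against germ-free; 12, 187, 12 and 40 of these had the higher effect in ileum. For EC+BSH2 against EC limma found 0, with 1872 at unadjusted p under 0.05. The response of Cyp7a1 to EC was lower in ileum than in liver by log2 -2.25 (adjusted p = 0.000556). In ileum it lay below the median of every array (1.39 in EC mice), so that difference rests on the liver. The response of Cdkn1a to BSH1 was lower in ileum by log2 -3.55 (adjusted p = 5.82e-06). Dbp fell in both tissues with BSH1, by less in ileum (difference in log2 1.67, adjusted p = 0.0303). Slc34a2 rose with BSH1 in liver too (log2 1.58, limma adjusted p = 0.00015), by more in ileum (difference in log2 2.00, adjusted p = 0.00809). In EC liver it lay below the lowest array median, so that liver difference is not exact. Liver Slc34a2 was also higher with BSH1 than with BSH2 (log2 1.43, limma adjusted p = 0.00127). Across the 15 clock genes, which are not independent replicates, the effects in ileum and liver correlated at r = 0.831 for EC against germ-free, 0.886 for EC+BSH1 against EC, 0.889 for EC+BSH1 against EC+BSH2, 0.875 for CONV-D against germ-free, and 0.0849 for EC+BSH2 against EC.

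Effects that share a control group were compared with what the shared controls give by themselves. Across all ileum transcript clusters, the effects of the 2 hydrolases correlated at r = 0.529, where simulated groups without an effect gave 0.5, and with separate control arrays for each effect r averaged 0.102. They shared 102 higher and 3 lower calls; with quantile normalization EC+BSH2 had 0 calls in limma to share. Shared control arrays raise such counts by themselves. In liver r was 0.515 against a simulated 0.499, and 0.0155 with separate controls. The effects of EC and of CONV-D against germ-free correlated at r = 0.418 in ileum (simulated 0.527, 0.0246 with separate controls) and 0.533 in liver (simulated 0.526, 0.0565 with separate controls). In liver they shared 8 higher and 18 lower calls, Cyp7a1 and Alas1 among the higher and Arntl and Tubb2a among the lower, all against the same 4 germ-free livers. Plin2 passed in opposite directions, log2 -0.72 for EC (adjusted p = 0.0426, held in 1 of 8 fits that each left out 1 array and ended with quantile normalization at 0.097) and 0.71 for CONV-D (adjusted p = 0.0392).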

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

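The tests of the signal range for the ileum calls and for the clock genes, those of the EC array with fewer decimals and of germ-free mice as the control for the ileum calls, those of the pancreas transcripts, and the test of time of day were chosen after the result was seen. The test of single arrays for the clock genes and the other splits of the arrays were written before.

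In 7 of 104 tests, each of 1 quantity in 1 group of arrays, 1 array lay far from the others, where chance gives about 5% of tests. The tests reuse the same arrays and so are not independent, and the genes among them were picked from these data. The mean of the exocrine pancreas markers was 3.78 in ileum EC+BSH1 replicate 1, against 10.44 to 11.61 in the other 3 arrays, and 9.43 in ileum germ-free replicate 3, against 11.06 to 11.28. The mean of the clock genes was 4.50 in ileum EC replicate 2 and 4.99 or above in the other EC arrays. The median of all transcript clusters was 3.13 in ileum EC+BSH2 replicate 3, with 3.20 as the nearest value. Dbp was 5.57 in liver EC+BSH2 replicate 3 (nearest 6.58), Slc22a13b was 6.64 in ileum EC+BSH2 replicate 1 (nearest 7.46) and Reg2 was 1.84 in ileum germ-free replicate 3 (nearest 3.73).

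For 45 effects of genes with the largest changes, the test of the difference between tissues passed in limma; the values are the log2 effect in ileum minus that in liver. For EC against germ-free mice they were Alas1 (-3.55), Clpx (1.59), Cyp7a1 (-2.25), Dab1 (-2.39), Elovl3 (2.13), Gclc (1.24), Gpcpd1 (-1.87), Nrep (-2.25), Ppp1r3c (2.27), Slc34a2 (-2.85), Sprr1a (-3.35), Tubb2a (4.46) and Usp2 (-1.45). For EC+BSH1 against EC they were Abcb1a (-1.95), Cdkn1a (-3.55), Dab1 (2.92), Dbp (1.67), Elovl3 (-3.45), Gpcpd1 (2.15), Nrep (2.56), Ppp1r3c (-2.54), Rgs16 (2.33), Slc34a2 (2.00), Tmem252 (2.62), Tubb2a (-3.76), Upp2 (2.45) and Vnn1 (2.26). For EC+BSH1 against EC+BSH2 they were Abcb1a (-2.09), Cdkn1a (-3.50), Chka (-1.45), Eci3 (1.24), Elovl3 (-2.06), Etnppl (2.07), Tmem252 (1.72), Tns4 (-1.54) and Upp2 (1.99). For CONV-D against germ-free mice they were Alas1 (-2.84), Cdkn1a (2.00), Cyp7a1 (-2.62), Hyou1 (1.56), Mgat4c (1.93), Paqr7 (-2.38), Sectm1a (-2.00), Slc10a2 (1.37) and Tifa (2.57). With quantile normalization 2 of the 45 ended, Dab1 (adjusted p = 0.0452 and then 0.0615) and Sprr1a (0.0478 and then 0.0662) for EC against germ-free mice. In 22 of the 45 both group means of a tissue lay below the lowest median of its arrays, so the difference rests on the other tissue. A fall in such a tissue could not be seen, whereas a large enough rise could have been.

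In ileum, 1062 of the 1157 calls for EC+BSH1 against EC were higher with the hydrolase. Against a single EC array as the whole cause stands that without EC replicate 2, the array with at most 2 decimals and the narrowest range, 612 calls were made, 542 higher and 70 lower. EC+BSH1 against germ-free ileum gave 4 calls with limma, with 1983 transcript clusters at unadjusted p under 0.05, so the EC group is the one that stands apart. A narrower signal range of the EC ileum arrays may account for part of the excess, since quantile normalization left 22.1% of the number of calls. Why the range is narrower stays open: the EC group has no second set of arrays, and a difference in the tissue itself was not tested.

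The clock genes changed with EC+BSH1 against EC in both tissues, and against a single liver array stands that at least 10 were called without any 1 array (10 without EC replicate 3). Against a narrower range of the EC arrays as the whole cause stands that, with the range of each array as a covariate, 12 of the 12 clock genes called in liver stayed past the threshold, and the 6 called in ileum kept a median of 101% of their log2 difference (75.3% to 125%), 5 of them past the threshold. The Nfil3 call in ileum ended because its difference fell and its SE rose (log2 1.67 ± 0.37 without and 1.26 ± 0.43 with the covariate). A candidate explanation is a different time of day at collection, since the effects of the clock genes correlated at r = 0.886 between ileum and liver across 15 genes. A shift of the clock by the hydrolase itself predicts the same, and the labels give no collection time, so both stay open. The same limit holds for EC against germ-free (r = 0.831), EC+BSH1 against EC+BSH2 (0.889) and CONV-D against germ-free (0.875). Liver Arntl was 3.6 in germ-free and 4.06 in EC+BSH1 mice, against 2.11 in EC, 2.18 in EC+BSH2 and 2.01 in CONV-D mice. Whether other changes in these comparisons, such as those of Cyp7a1 and Alas1, go with collection time was not tested.

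Transcripts of pancreatic digestive enzymes were abundant in ileum arrays and present in liver arrays. Pancreatic tissue carried into the samples may account for them, since the 9 markers rose and fell together over the liver arrays within groups (median r = 0.968 over 36 pairs, where the highest of 1000 random lists gave 0.58). An effect of the first hydrolase on them stays open, but 1 array carries most of the difference: of the 4 EC+BSH1 ileum arrays 2 lay below the lowest EC array (10.59), replicate 1 at 3.78 and replicate 4 at 10.44, and in liver the lower list was lost without replicate 1 (adjusted p = 0.174) and with an estimated correlation (0.711). Intestine taken nearer to the pancreas than the ileum cannot be told apart from this: 3 of the 4 measured genes typical of ileum (Fabp6, Slc10a2 and Fgf15) lay below the lowest array median, but their low values were known when the test was written, and the other, Amn, was high (5.68). Genes of proximal intestine lay above the array medians (Pdx1 4.58, Gata4 7.12, Cybrd1 7.34, Gip 9.18 and Lct 10.38). Lct and Gip were at percentiles 99.6 and 98.9 of all transcript clusters. That goes with such a segment but does not settle it, since no arrays of a second segment are at hand. Others of them, Slc40a1 and Onecut2, were as high in liver (6.85 and 6.94), so they are not particular to intestine. The label ileum was used as given, and the results on bile acid genes there carry this limit.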

How the results depend on the processing

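The covariate for the signal range of each array and the fits without the doubted arrays were chosen after seeing the data; the other alternatives and the other splits of the arrays were fixed before. No named gene and no list changed direction past the threshold in the alternatives where this was checked. These were quantile normalization, median centring, the label code as covariate, the replicate block and each array of the comparison left out. Lists were also run without dim transcript clusters and with an estimated correlation. Under the other alternatives the direction of each was not checked. Of 193 calls on named genes, 43 were lost with quantile normalization, 21 with median centring and 46 with the number in the label code as a covariate. Of 56 list calls at the preset correlation, 49 were lost with an estimated correlation, 7 with quantile normalization and 11 without dim transcript clusters. The cause was not tested for any change below. Fewer arrays or another threshold change the number of calls by themselves, and this was not separated from other causes. The number of arrays and the range of signal over background limit the precision.

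Counts are of transcript clusters past the threshold in limma. Numbers at unadjusted p under 0.05 are to be read against the share of about 0.05 of 23332 that chance gives. For EC against germ-free ileum, 310 became 79 with quantile normalization, 134 with median centring, 531 without dim transcript clusters, 512 with all 42 arrays in a single fit, 470 with 1 transcript cluster per gene, 3 with the signal range as covariate, 177 without the doubted arrays, 3 with only the groups compared and 729 at adjusted p 0.1. For EC+BSH1 against EC, 1157 became 256 with quantile normalization, 507 with array weights, 122 with the signal range as covariate, 38 without the doubted arrays, 0 with only the groups compared (2981 at unadjusted p under 0.05) and 1964 at adjusted p 0.1. For EC+BSH2 against EC, 145 became 0 with quantile normalization, 0 with the signal range as covariate and 0 with only the groups compared (1980, 1240 and 2917 at unadjusted p under 0.05), 11 with median centring, 392 without dim transcript clusters, 56 without an intensity trend, 428 with all arrays in a single fit, 55 with array weights, 84 with the label code, 277 with 1 transcript cluster per gene, 1 without the doubted arrays and 680 at adjusted p 0.1. For EC+BSH1 against EC+BSH2, 40 became 72 with all arrays in a single fit, 26 with array weights, 19 with the label code, 7 without the doubted arrays and 4 with only the groups compared. For CONV-D against germ-free ileum, 71 became 120 with quantile normalization, 124 with all arrays in a single fit, 150 with array weights and 18 with only the groups compared.

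For EC against germ-free liver, 61 became 103 with quantile normalization, 107 without dim transcript clusters, 136 with all arrays in a single fit, 107 with 1 transcript cluster per gene, 37 without the doubted array, 10 with only the groups compared and 120 at adjusted p 0.1. For EC+BSH1 against EC in liver, 173 became 303 with quantile normalization, 283 with all arrays in a single fit, 272 with the signal range as covariate, 24 with only the groups compared and 284 at adjusted p 0.1. For EC+BSH2 against EC in liver, 1 became 15 with all arrays in a single fit and 0 with each of quantile normalization, median centring, no intensity trend, array weights, the label code, the signal range as covariate, the doubted array left out and only the groups compared (in this order 1541, 1482, 1622, 1710, 1911, 1405, 1167 and 1174 at unadjusted p under 0.05). For EC+BSH1 against EC+BSH2 in liver, 58 became 90 with quantile normalization, 103 with all arrays in a single fit, 132 with array weights, 26 with the label code, 95 with the signal range as covariate, 8 with only the groups compared and 97 at adjusted p 0.1. For CONV-D against germ-free liver, 44 became 13 with the label code and 15 with only the groups compared. The differences between tissues changed from 0 to 2 for EC+BSH2 against EC with group and number as a random block, and with quantile normalization from 21 to 38 for EC+BSH1 against EC+BSH2 and from 70 to 116 for CONV-D against germ-free mice. The correlation of the EC and CONV-D effects in ileum was 0.459 with quantile normalization. With separate controls, the mean r of the hydrolase effects in ileum was 0.102 as deposited, 0.0544 with quantile normalization and 0.14 without dim transcript clusters, and in liver 0.0155, 0.0192 and 0.0474. For the EC and CONV-D effects it was, in the same order, 0.0246, 0.0463 and 0.0851 in ileum and 0.0565, 0.071 and 0.113 in liver.

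Replicate numbers did not pair the arrays within a tissue: at most 1 of 4 pairs of a comparison had a correlation over 0.1. With the replicate number as a block, the count for EC+BSH2 against EC in ileum was 362, for EC against germ-free liver 38 and for CONV-D against germ-free liver 17; 30 calls on named genes and 10 list calls were lost.

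With each array left out in turn, the ileum counts ran from 103 (without germ-free replicate 3) to 658 (without EC replicate 1) for EC against germ-free, from 412 (EC+BSH1 replicate 1) to 1833 (EC+BSH1 replicate 2) for EC+BSH1 against EC, from 0 (EC replicate 2, and also EC replicate 4 and EC+BSH2 replicate 1) to 517 (EC replicate 1) for EC+BSH2 against EC, from 17 (EC+BSH2 replicate 1) to 51 (EC+BSH1 replicate 2) between the hydrolases and from 38 (germ-free replicate 1) to 75 (CONV-D replicate 4) for CONV-D against germ-free. In liver they ran in the same order from 30 (germ-free replicate 4) to 61 (EC replicate 1), from 94 (EC+BSH1 replicate 3) to 175 (EC+BSH1 replicate 4), from 0 (EC replicate 2, and each of the other arrays) to 4 (EC replicate 1), from 29 (EC+BSH2 replicate 1) to 77 (EC+BSH2 replicate 3) and from 24 (germ-free replicate 4) to 48 (CONV-D replicate 4).

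In 9 of the 10 comparisons the real grouping was the 1 split with as many calls, of 35 splits, or of 100 drawn for CONV-D against germ-free. That share, 2.86% or 1%, lies under the limit set beforehand and is the smallest that these splits can give. It was not corrected for the 10 comparisons, which share groups, so chance is not excluded for each of them. The splits also cannot tell an effect from a difference in array quality between groups. The highest other split gave 1, 226, 3, 6 and 15 calls in ileum and 1, 2, 5 and 4 in liver. For EC+BSH2 against EC in liver, 4 of 35 splits gave as many as the 1 real call and the highest other gave 4, so chance cannot be excluded.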

Other observations

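Chosen after the data were seen were the comparisons of the hydrolase groups with germ-free mice and of CONV-D with EC, and the test of replicate numbers across tissues; the list tests of CONV-D against germ-free mice were planned.

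Against germ-free mice, EC+BSH1 gave 4 calls in ileum, 2 higher and 2 lower, with Reg3g among them. EC+BSH2 gave 0 in limma, and 10 calls with quantile normalization. As deposited, 1070 transcript clusters were at unadjusted p under 0.05 for EC+BSH2, no more than chance gives without an effect. In liver EC+BSH1 gave 7 calls, which included Npas2, Ppard, Cdkn1a and Slc34a2, and EC+BSH2 gave 2, which were Cyp7a1 and Arntl. With quantile normalization these liver counts were 14 and 6. CONV-D against EC gave 831 calls in ileum, 795 higher and 36 lower, and 97 with quantile normalization. In liver it gave 8 calls, all higher in CONV-D mice, among them the sterol 12-hydroxylase Cyp8b1, the lipid droplet protein Plin2 and the glycerol phosphate dehydrogenase Gpd2, and 10 with quantile normalization. These names were chosen after their values were seen.

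Further lists of the CONV-D comparison passed camera and were lost with an estimated correlation. In ileum these included proliferation genes, higher (median log2 0.26, adjusted p = 0.00287, and adjusted p = 0.209 with an estimated correlation), and xenobiotic metabolism genes, lower (median log2 -0.14, adjusted p = 0.0236, and adjusted p = 0.294 with an estimated correlation). The latter call was also lost without germ-free replicate 3 (0.0728), without CONV-D replicate 3 (0.238) and with replicate number as a block (0.0623). In liver, MHC class II genes were higher (median log2 0.51, adjusted p = 0.00206, and adjusted p = 0.136 with an estimated correlation), and so were interferon genes (median log2 0.25, adjusted p = 0.0018, and adjusted p = 0.154 with an estimated correlation). The interferon call in liver was also lost with the number in the label code as a covariate (adjusted p = 0.31).

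A hypothesis is that an ileum and a liver array of 1 group with the same replicate number may come from the same mouse. Over 3874 transcript clusters bright in both tissues, deviations from the group means correlated at a mean r of 0.101 for the 21 pairs with the same number and -0.0308 for other pairs. Of random renumberings within groups, 0.01% gave a mean as high, and 10 of 21 arrays matched their own number best, where 5 are expected. Without transcript clusters that follow the pancreas list the mean r was 0.0669, so part of the likeness goes with pancreatic transcripts. The labels do not state such pairing, and it was not used in any test except the random block.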
